A study of Mus musculus with 34 samples.

How the data were processed

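Histone marks were profiled by ULI-NChIP-seq, a chromatin immunoprecipitation of native, unfixed chromatin adapted to very small numbers of cells, in mouse microglia of the hippocampus. The animals carried a Tmem119-tdTomato reporter, which makes microglia fluorescent, and per the labels their age was 3 weeks after birth. Control animals (Ctrl) were set against animals named FGR in the labels, in a series on growth restriction in the uterus. H3K4me3 (a mark of active promoters), H3K9ac and H3K27ac (marks of active promoters and enhancers) and H3K9me3 (a mark of heterochromatin) were each measured in 4 libraries per group. The label of replicate 4 gives no age. The labels do not say whether replicates came from separate animals or pools, so all p-values measure only the spread between these samples, which may be technical. The input library of each group came without a peak list and was not used here.

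Per the submitters' processing notes, which name tools and versions without their roles or order, Trim Galore 0.6.5, Bowtie2 2.4.5, SAMtools 1.3.1, MACS2 2.2.7.1 and DiffBind 3.12.0 were used with the mm10 build. The deposited files were 32 peak lists, 1 per library, in the column layout of MACS2. The lists were narrow peaks except for replicates 1 to 3 of H3K9me3, which were broad peaks. Each deposited peak carries a fold enrichment over the local background, a ratio made by the authors. It also carries −log10 p-value and −log10 q-value columns, deposited as such, and a whole-number score deposited by the authors that follows one of them. These values belong to a single list and were used only to describe, rank or filter peaks within it. The options of the peak caller and the control library are not given in the sources used here.

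The thresholds of the deposited lists were read from their lowest values. The lowest −log10 q of the narrow lists lay between 1.302 and 1.413. The H3K9me3 broad lists of Ctrl reached down to a −log10 p of 1.00 with −log10 q values of 0, and their score followed the p-value. Those of FGR ended at −log10 q values of 1.01 to 1.05, and their score followed the q-value. The 2 groups were thus cut at different thresholds for this mark.

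No read counts came with the lists, and sequencing depth is therefore unknown. As a substitute, the whole-number pileup at each summit and the local background were solved from the fold and −log10 p of each narrow peak. The lowest background per library, which also grows with the fragment setting, served as a relative measure of depth. It was 2.835 to 3.578 in Ctrl and 0.846 to 1.163 in FGR for H3K4me3, 2.347 to 2.63 and 0.523 to 0.659 for H3K9ac, and 2.388 to 2.751 and 0.621 to 0.767 for H3K27ac. The smallest peak width, which MACS2 sets from the fragment length, was 275 to 280 bp in Ctrl and 148 to 150 bp in FGR for H3K4me3, 262 to 271 bp and 252 to 260 bp for H3K9ac, and 267 to 284 bp and 148 to 151 bp for H3K27ac. Ctrl and FGR libraries therefore differed in background and in fragment setting for these 3 marks, by little in fragment setting for H3K9ac, and no library of either group shared the other group's range of either.

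Peaks were placed on 21631 protein-coding genes of autosomes 1 to 19 and X in a RefSeq table of GRCm38.p6, the assembly that mm10 is built from. As a check of the build, 9990 to 13228 genes per H3K4me3 library had a peak within 1 kb of a gene end, against 1198 to 3139 after the gene ends were moved by 200 kb. The table gives no strand, so the start of a gene could not be told from its end. Contrary to the design fixed before the data were examined, which named the 5′ end, windows were placed around both ends of each gene. Covered length per gene was the length in kb of called peaks within 2.5 kb of either end, and a gene had a peak at an end if a peak lay within 1 kb of either end. For H3K9me3 the percent of the gene body under peaks was used. Neighbouring genes can share a window, and many clustered protocadherins do, so members of a list are not always independent. Sharing is not marked at every gene named below. A gene entered the test if at least 2 libraries of the mark had a peak in its window.

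Covered lengths were compared with limma (lmFit and eBayes, version 3.58.1 in R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every adjusted p of a gene is from this test, two-sided. Counts per library were compared with two-sided exact permutation tests, on log2 values for peak numbers and covered genome. With 4 against 4 libraries the smallest p is 0.0286, and with 3 against 3 libraries, as for H3K9me3, it is 0.1. Peaks of all libraries of a mark were merged into regions, and regions with a peak in every library of 1 group and in no library of the other were counted. With a library left out this rule is looser, so the counts can rise for that reason alone. Peaks called exactly alike in 2 replicates made up at most 0.545% of a list, so all replicates were counted as separate samples. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

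A total of 22 gene lists were fixed before the data were examined: homeostatic microglia, disease-associated microglia, inflammatory response, interferon response, complement and phagocytosis, antigen presentation, glycolysis, oxidative phosphorylation, cell cycle, histone modifying enzymes, border-associated macrophages, neurons, astrocytes, oligodendrocyte lineage, endothelial and mural cells, lymphocytes and neutrophils, housekeeping, Hox genes, zinc finger genes named Zfp with a number (many of the KRAB type), clustered protocadherins, olfactory and vomeronasal receptors, and histone genes. Mx1 and Mx2 of the interferon list were not found among the genes. Lists were tested against all other genes with camera at a preset correlation of 0.01, and again with an estimated correlation, each adjusted over the lists of a mark. A camera call says that a list moved more or less than other genes, not that it rose or fell. It compares differences in kb, or in points for H3K9me3, and not in proportion to the Ctrl coverage of a list.

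Named genes followed a rule fixed before the data were examined. Per mark and direction it took the 8 genes with the smallest p whose groups did not overlap, leaving out clone names. It added the 2 called members with the smallest p of each list, and 8 fixed microglial genes whatever their values. From the genes this rule gave, a smaller number was chosen for length after their values were seen, and a few are not reported here. Genes named only because they lie under a long region called in a single group were also chosen after the regions were seen.

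The limma step was tested on simulated data with 100 genes changed by each of 2 amounts. A change of 1 kb was recovered for 73% of genes in H3K4me3, 53% in H3K9ac and 68% in H3K27ac, and a change of 0.5 kb for 19%, 2% and 6%. For H3K9me3, a change of 10 points of the gene body was recovered for 12% of genes and a change of 5 points for none. False calls numbered 2, 2, 3 and 0. The simulated data held few changed genes and no shift common to all genes, unlike the lists compared here. These rates therefore do not describe the tests of the deposited lists.

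Alternatives planned before the data were examined were a stricter threshold of −log10 q of at least 5, lists shortened to equal lengths by rank, quantile normalization between libraries, windows of 1 kb and 5 kb, gene bodies with 10 kb on each side, peaks in at least 1 or at least 4 libraries, at least 50% of a region covered, H3K9me3 with replicate 4 included, the replicate number as a block, fry in place of camera, and leaving out each library in turn. Added after seeing the data was a depth-matched setting. Pileup and background were scaled to the lowest background of the mark, and peaks kept at a −log10 p of at least 4. Kept peaks retained their deposited start and end, so covered lengths were not matched for depth. The background used for scaling was not divided by fragment length. Per 100 bp of fragment, H3K27ac background was 0.856 to 1.00 in Ctrl and 0.417 to 0.518 in FGR, in proportion closer than undivided. For H3K4me3 and H3K27ac, the setting therefore thinned Ctrl lists further than depth alone would. Also added were peaks stitched over gaps of up to 500 bp, a single gene end chosen by H3K4me3 peaks, a common threshold of −log10 q of at least 1 for H3K9me3, and replicates 1 to 3 of both groups.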

Results

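Peak lists of 4 histone marks were compared between hippocampal microglia of control mice (Ctrl) and of FGR mice, with 4 libraries per mark and group. The labels give an age of 3 weeks for replicates 1 to 3 and none for replicate 4. The question of the series was how growth restriction before birth affects H3K4me3, H3K9ac, H3K27ac and H3K9me3 in these cells. Lists held 16598 to 18391 peaks in Ctrl and 43175 to 49045 in FGR for H3K4me3, 42220 to 47729 and 54853 to 87128 for H3K9ac, and 45988 to 50116 and 53492 to 78143 for H3K27ac. The H3K9me3 broad lists of replicates 1 to 3 held 345501 to 492938 peaks in Ctrl and 15522 to 22903 in FGR. Coordinates are those of mm10, and gene values are kb of called peaks within 2.5 kb of either gene end, as mean ± SD. A mix-up of the H3K4me3 and H3K9ac labels in FGR cannot be excluded. Across genes, FGR H3K4me3 libraries correlated better with Ctrl H3K9ac libraries (mean r of 0.908) than with Ctrl H3K4me3 libraries (0.822). FGR H3K9ac libraries went against a mix-up, with 0.757 for Ctrl H3K9ac and 0.65 for Ctrl H3K4me3. Ctrl H3K4me3 libraries correlated with each other at only 0.872, against 0.977 among Ctrl H3K9ac libraries. Gains and losses of these marks are given under the deposited labels.

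**Figure D1:**
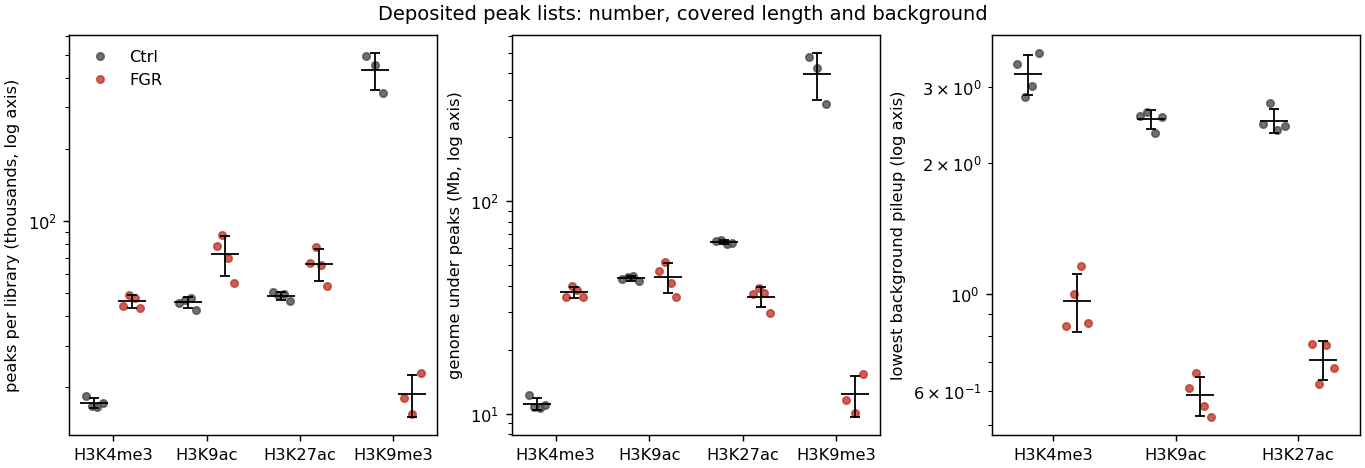
Peaks per library (axis in units of 1000), Mb of genome under peaks and the lowest background pileup of each library, all on log axes, for Ctrl (grey) and FGR (red); points are libraries, with the mean and SD as bars. FGR libraries held more H3K4me3 peaks over a lower background, with means of 17218 peaks in Ctrl and 45945 in FGR. Background was not computed for the H3K9me3 broad lists.

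The comparison of H3K4me3, a mark of active promoters, gave longer peak coverage in FGR at nearly all genes tested. At P2ry12, a purinergic receptor of homeostatic microglia (chromosome 3, 59216271 to 59262985), coverage was 2.49 ± 0.344 kb in Ctrl and 7.99 ± 0.165 kb in FGR (SD, n = 4 each; limma adjusted p = 1.75e-07). Tmem119, a marker of resident microglia (chromosome 5, 113793729 to 113800396), had 2.15 ± 0.225 kb and 4.89 ± 0.709 kb. Sall1, a transcription factor of microglial identity, had 3.21 ± 0.565 kb and 6.24 ± 0.231 kb. Among 14043 genes, 13410 were covered more in FGR and 0 less by limma, with 0 genes less also at an unadjusted p under 0.05. The median difference was 0.887 kb. After quantile normalization between libraries, which removes such a shift, 2220 genes were higher and 3398 lower.

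H3K4me3 coverage rose at all 24 tested homeostatic microglia genes, with list medians of 2.11 kb in Ctrl and 3.72 kb in FGR, and quantile normalization left 8 higher and 5 lower. Rhob, a small GTPase, went from 2.85 ± 0.463 kb to 7.06 ± 0.258 kb, and the fractalkine receptor gene Cx3cr1 from 2.72 ± 0.711 kb to 5.21 ± 0.0731 kb. A region called only in the 4 FGR libraries lay in Cx3cr1, on chromosome 9 from 120054956 to 120058900. Csf1r, the receptor for colony stimulating factor on which microglia depend, went from 2.39 ± 0.121 kb to 3.56 ± 0.289 kb, but was lower in FGR after quantile normalization. The same turn was seen at Trem2, a lipid-sensing receptor of microglia, with 2.33 ± 0.263 kb and 3.5 ± 0.143 kb, and Cx3cr1 no longer passed the test.

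Lists of genes with immune functions moved the same way in the deposited H3K4me3 lists. Coverage rose at all 24 disease-associated microglia genes, 21 of 22 inflammatory genes, 20 of 20 interferon genes, 21 of 21 complement and phagocytosis genes, 13 of 15 antigen presentation genes and 9 of 9 border-associated macrophage genes. Tyrobp, the adaptor of Trem2, whose window is shared with Hcst, went from 1.29 ± 0.221 kb to 6.21 ± 0.295 kb. Apoe, a lipid carrier whose window is shared with Tomm40, went from 0.14 ± 0.281 kb to 2.63 ± 0.44 kb. The NF-κB inhibitor gene Nfkbia went from 0.592 ± 0.167 kb to 4.66 ± 0.449 kb, Tlr2, a receptor for bacterial lipoproteins, from 0.845 ± 0.172 kb to 2.91 ± 0.147 kb, and B2m, the light chain of MHC class I, from 1.024 ± 0.423 kb to 5.69 ± 0.259 kb. Among macrophage markers, Mrc1 went from 0.0727 ± 0.145 kb to 2.17 ± 0.0278 kb and Maf, a transcription factor, from 4.13 ± 0.348 kb to 8.37 ± 0.0297 kb. After quantile normalization, 2 antigen presentation genes were higher and 3 lower, while more genes of the other 5 lists were higher than lower.

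The rise of H3K4me3 was not limited to these lists. It took in 15 of 15 housekeeping genes, 36 of 36 histone modifying enzymes, 65 of 65 histone genes, 13 of 13 glycolysis, 23 of 23 oxidative phosphorylation and 23 of 24 cell cycle genes. Actb, for β-actin, went from 2.62 ± 0.333 kb to 7.39 ± 0.219 kb, the deacetylase gene Hdac3 from 1.54 ± 0.161 kb to 3.69 ± 0.0792 kb, and H2bc7, a gene of a histone cluster with shared windows, from 1.03 ± 0.153 kb to 4.72 ± 0.166 kb. Camera placed housekeeping genes (adjusted p = 0.00318), histone modifying enzymes (0.00867) and histone genes (0.0121) above other genes. Their adjusted p = 0.404, 0.413 and 0.45 with an estimated correlation. After quantile normalization, 9 housekeeping genes were higher and none lower, 14 enzymes were higher and 5 lower, 18 histone genes higher and 14 lower, and the direction turned for oxidative phosphorylation, with 1 higher and 4 lower.

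Lists of other cell types also had longer H3K4me3 coverage in FGR, at 8 of 11 neuronal genes, 6 of 6 astrocyte, 6 of 7 oligodendrocyte, 9 of 10 endothelial and mural and 5 of 7 lymphocyte and neutrophil genes. It was longer at 28 of 34 Hox genes, 319 of 328 Zfp genes, 24 of 25 protocadherins and 12 of 15 olfactory and vomeronasal receptors. Nefh, a neurofilament gene with a window shared with Ap1b1, had 0.0762 ± 0.152 kb in Ctrl and 1.1 ± 0.0331 kb in FGR. The developmental gene Hoxb4 had 0.389 ± 0.277 kb and 2.26 ± 0.0238 kb. Hox genes (camera adjusted p = 0.000112) and neuronal genes (0.012) rose by fewer kb than other genes, with adjusted p = 0.368 and 0.368 with an estimated correlation. Their list medians were short in Ctrl, so this is not a smaller rise in proportion. They were 0.19 kb in Ctrl and 0.978 kb in FGR for Hox genes, and 0.076 kb and 1.1 kb for neuronal genes. After quantile normalization the direction turned for Hox genes (2 higher, 9 lower), neurons (0 higher, 4 lower), Zfp genes (38 higher, 106 lower), astrocytes, endothelial and mural cells, lymphocytes and neutrophils, and olfactory and vomeronasal receptors, but not for protocadherins (17 higher, 1 lower). Adjusted over the list alone, the counts of all 22 lists were those over all genes.

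Several genes with the smallest p had no H3K4me3 peak near either end in Ctrl. Slitrk5, for a neuronal transmembrane protein (chromosome 14, 111675115 to 111683144), was listed at 0 in all Ctrl libraries and had 2.67 ± 0.0548 kb in FGR (limma adjusted p = 1.71e-07). The same held for 3 genes of the X chromosome: the transcriptional corepressor gene Bcor with 2.52 ± 0.0799 kb in FGR, Brwd3 with 2.23 ± 0.0342 kb and the receptor gene P2ry10b with 2.07 ± 0.0104 kb. Tsc22d3, a glucocorticoid-induced gene on X, had 0.0293 ± 0.0585 kb in Ctrl and 3.77 ± 0.182 kb in FGR, and the adrenergic receptor gene Adrb1 2.84 ± 0.196 kb and 6.68 ± 0.0692 kb.

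At the library level, H3K4me3 peaks were 2.67-fold more numerous in FGR, with a log2 difference of 1.42 (SE 0.0547, exact permutation p = 0.0286). Covered genome rose from 11.1 ± 0.759 Mb to 37.3 ± 2.2 Mb and genes with a peak at an end from 10107 ± 203 to 13097 ± 107, each with n = 4 and an exact p = 0.0286. A total of 14021 regions were called only in FGR and 12 only in Ctrl, the longest being a 4376 bp region at Cmtm6 on chromosome 9, from 114743727 to 114748102. The share of peaks at gene ends fell from 64.0 ± 1.14% to 33.1 ± 1.71% (n = 4, exact p = 0.0286), but with lists of equal length it was 64.7% in Ctrl and 67.9% in FGR. Background was lower and the smallest peak width shorter in every FGR library, beside all gene groups above, and with equal list lengths the exclusive regions numbered 936 and 178.

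**Figure D2:**
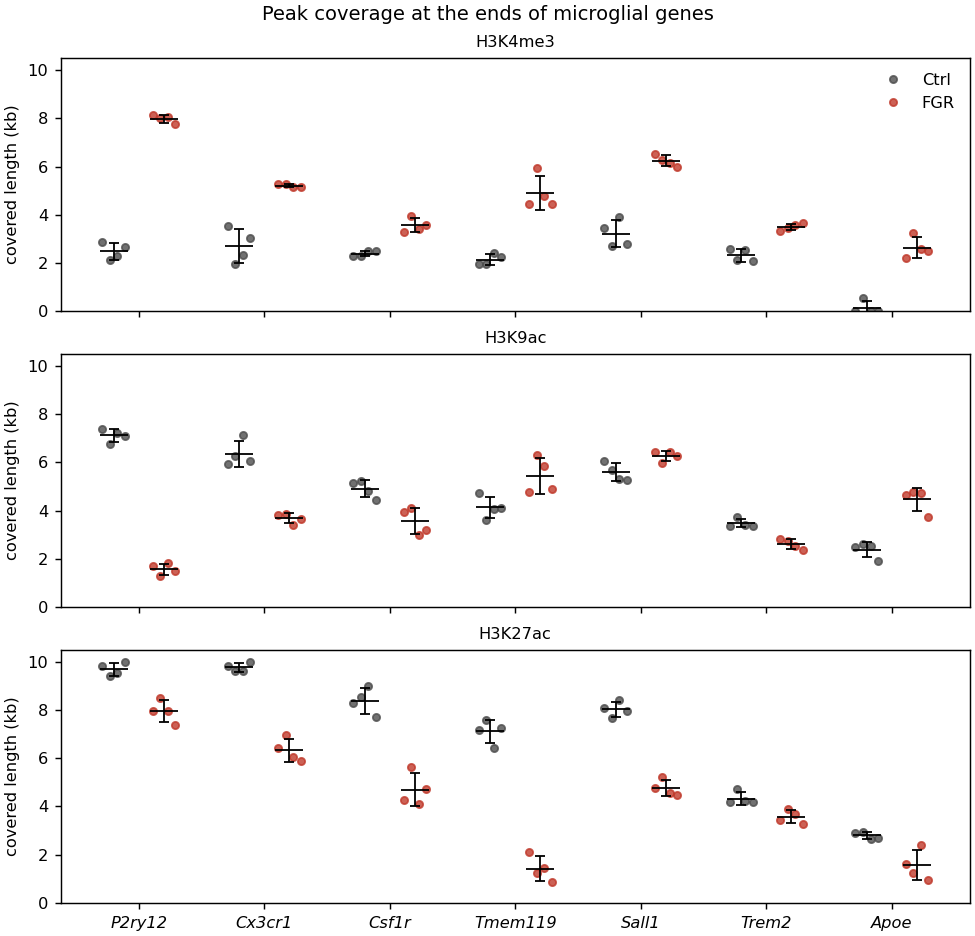
Kb of called peaks within 2.5 kb of either end of 7 microglial genes, for H3K4me3, H3K9ac and H3K27ac; points are Ctrl (grey) and FGR (red) libraries, with the mean and SD as bars. At P2ry12, H3K4me3 coverage was longer in FGR (2.49 against 7.99 kb) and H3K9ac coverage shorter (7.12 against 1.57 kb). A mix-up of these 2 labels in FGR cannot be excluded. After quantile normalization, H3K4me3 at Csf1r, Cx3cr1 and Trem2 and H3K27ac at P2ry12 and Trem2 changed direction.

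H3K9ac, an acetylation mark of active promoters and enhancers, moved in both directions. Among the genes with less of it, Cd53, for a leukocyte surface protein (chromosome 3, 106758861 to 106790149), had 3.14 ± 0.102 kb in Ctrl and was listed at 0 in all FGR libraries (n = 4 each; limma adjusted p = 2.81e-07). P2ry12 fell from 7.12 ± 0.254 kb to 1.57 ± 0.233 kb (adjusted p = 3.32e-07). Coverage appeared or rose at developmental and neuronal genes such as Hoxa6 (0.0663 ± 0.133 kb to 2.67 ± 0.352 kb, window shared with Hoxa5) and Dlx2, a transcription factor of forebrain interneurons (0.415 ± 0.309 kb to 2.81 ± 0.289 kb). Of 15605 genes tested by limma, 4446 were covered more and 4682 less in FGR, and with lists of equal length 3251 more and 5443 less. H3K9ac peaks were also narrower in FGR, with median widths of 407 to 459 bp against 634 to 696 bp in Ctrl. Where coverage fell, narrower calls and less of the mark were not told apart, for the genes and lists below as well.

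Among 25 tested homeostatic microglia genes, H3K9ac fell at 13, rose at 5 and did not pass the test at 7. Fcrls fell from 4.44 ± 0.269 kb to 0.743 ± 0.139 kb, Cx3cr1 from 6.35 ± 0.549 kb to 3.69 ± 0.204 kb and Csf1r from 4.91 ± 0.359 kb to 3.57 ± 0.549 kb. Tmem119 went the other way, from 4.13 ± 0.455 kb to 5.45 ± 0.747 kb (adjusted p = 0.0138), but was lower in FGR when a single gene end was used. Sall1 rose from 5.59 ± 0.366 kb to 6.28 ± 0.211 kb. The list fell relative to other genes (camera adjusted p = 0.00724), with adjusted p = 0.507 with an estimated correlation. Adjusted over the list alone, 15 genes fell and 5 rose.

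H3K9ac fell at 14 and rose at 7 of 28 inflammatory genes. Casp1, the inflammasome protease gene, fell from 3.4 ± 0.0558 kb to 0.172 ± 0.198 kb and the cytokine gene Il1a from 5.07 ± 0.214 kb to 1.41 ± 0.187 kb. Il1b, its paralog, fell from 1.82 ± 0.771 kb to 0.405 ± 0.35 kb (adjusted p = 0.00845). Camera gave this list an adjusted p = 0.0351 (adjusted p = 0.577 with an estimated correlation). Disease-associated microglia genes fell at 11 and rose at 4 of 24, a direction that turned in the depth-matched setting, with 9 more and 7 less. Ccl4, a chemokine gene with a window shared with Ccl3, fell from 4.53 ± 0.0566 kb to 0.982 ± 0.105 kb and Trem2 from 3.47 ± 0.166 kb to 2.62 ± 0.212 kb, while Apoe rose from 2.39 ± 0.319 kb to 4.47 ± 0.488 kb. Complement and phagocytosis genes fell at 11 and rose at 4 of 23, among them C3ar1, a complement receptor gene (3.44 ± 0.265 kb to 0.949 ± 0.376 kb), and Mertk, a receptor for the uptake of dying cells (5.28 ± 0.0995 kb to 3.09 ± 0.312 kb).

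Of 20 interferon genes, 6 lost and 1 gained H3K9ac (adjusted over the list alone, 6 and 0), with Ifit3 at 2.15 ± 0.073 kb in Ctrl and 0.0635 ± 0.127 kb in FGR. Antigen presentation genes were split, 4 more and 4 less of 18 (adjusted over the list alone, 3 and 4), with Cd74, the invariant chain of MHC class II, falling from 2.75 ± 0.0313 kb to 1.29 ± 0.262 kb. Also among the genes with the smallest p for a fall were Evi2b (3.5 ± 0.106 kb to 0, window shared with Evi2 and Evi2a), the leukocyte surface gene Cd84 (2.85 ± 0.0602 kb to 0), and Tlr7, a receptor for single-stranded RNA (3.02 ± 0.0675 kb to 0.333 ± 0.0581 kb). Border-associated macrophage genes rose at 3 and fell at 2 of 11, with Maf falling from 8.03 ± 0.268 kb to 3.81 ± 0.0907 kb. The directions of the last list, of antigen presentation, glycolysis and endothelial genes and of the receptor genes varied with scaling.

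H3K9ac rose at 10 of 14 neuronal, 7 of 13 astrocyte and 8 of 14 oligodendrocyte genes and fell at 1 of these, an astrocyte gene. Rbfox3, which encodes the neuronal protein NeuN and shares a window with Engase, rose from 0.195 ± 0.227 kb to 2.19 ± 0.36 kb. Pdgfra, a receptor of oligodendrocyte precursors, rose from 0 to 0.978 ± 0.175 kb. Camera placed neurons (adjusted p = 0.000497) and the oligodendrocyte lineage (0.021) above other genes, with adjusted p = 0.506 and 0.524 with an estimated correlation. Endothelial and mural genes rose at 3 and fell at 1 of 10, and lymphocyte and neutrophil genes rose at 3 of 10 (2 adjusted over the list alone). Hox genes rose at 28 of 35, and at 14 after quantile normalization, with a camera adjusted p = 2.42e-06 (adjusted p = 0.506 with an estimated correlation). Among other genes with the smallest p for a rise were Ephb2 (0 to 1.98 ± 0.111 kb), for a receptor of axon guidance, Efna3 (0.535 ± 0.179 kb to 2.52 ± 0.0631 kb), for an ephrin, and Ascl2 (0 to 1.99 ± 0.192 kb), for a transcription factor.

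Histone genes lost H3K9ac at 50 of 67 members and gained it at 2. The list fell relative to other genes (camera adjusted p = 2.88e-09, and adjusted p = 0.167 with an estimated correlation). H2ac6, in a histone cluster on chromosome 13, fell from 3.11 ± 0.0491 kb to 1.43 ± 0.118 kb. H3K9ac also fell at 156 and rose at 32 of 331 Zfp genes (adjusted over the list alone, 155 and 32; camera adjusted p = 2.69e-05; adjusted p = 0.507 with an estimated correlation). Zfp91 fell from 4.63 ± 0.157 kb to 2.24 ± 0.238 kb. Oxidative phosphorylation genes fell at 12 and rose at 1 of 23 (camera adjusted p = 0.0262; adjusted p = 0.507 with an estimated correlation), with Uqcrc2, of respiratory complex III, falling from 2.6 ± 0.188 kb to 1.55 ± 0.072 kb. Housekeeping genes fell at 8 and rose at 1 of 15. Glycolysis genes rose at 4 and fell at 3 of 15, cell cycle genes rose at 6 and fell at 6 of 24, and histone modifying enzymes rose at 11 and fell at 12 of 37. Protocadherins rose at 5 of 24, and at 0 adjusted over the list alone by limma, with 9 at an unadjusted p under 0.05 (camera adjusted p = 0.0174; adjusted p = 0.648 with an estimated correlation). Olfactory and vomeronasal receptors rose at 13 and fell at 9 of 38.

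H3K9ac peaks numbered 45521 ± 2392 in Ctrl and 72648 ± 13780 in FGR (n = 4, exact permutation p = 0.0286), but a stricter threshold gave a log2 difference of 0.34 with an exact p = 0.0857. Covered genome was 43.4 ± 1.21 Mb and 44.0 ± 7.1 Mb (n = 4, exact p = 0.971), so a difference was not resolved against the spread, but with lists of equal length it was 42.1 and 33.0 Mb (exact p = 0.0286). Genes with a peak at an end rose from 11544 ± 100 to 13917 ± 504 (n = 4, exact p = 0.0286). The share of peaks at gene ends was 27.4 ± 1.17% and 23.5 ± 2.68% (n = 4, exact p = 0.0857), with lists of equal length 28.9% and 32.1%, and in the depth-matched setting 51.7% and 24.4% (exact p = 0.0286 for both settings). Regions called only in FGR numbered 9586, or 14489 without FGR replicate 3, and only in Ctrl 5073. This order turned with lists of equal length, with 4060 and 6447, and with at least 50% of a region covered, with 5846 and 7598. A Ctrl region of 5417 bp, on chromosome X from 13631517 to 13636933, lay at Gpr34, a receptor gene of the homeostatic list, and at Cask. Background was lower in every FGR library beside all of these groups, and in the depth-matched setting 5428 genes were covered more and 3894 less, with 651 Ctrl regions. That setting dropped whole peaks and left the widths of the others as deposited, so covered lengths were not matched for depth.

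**Figure D3:**
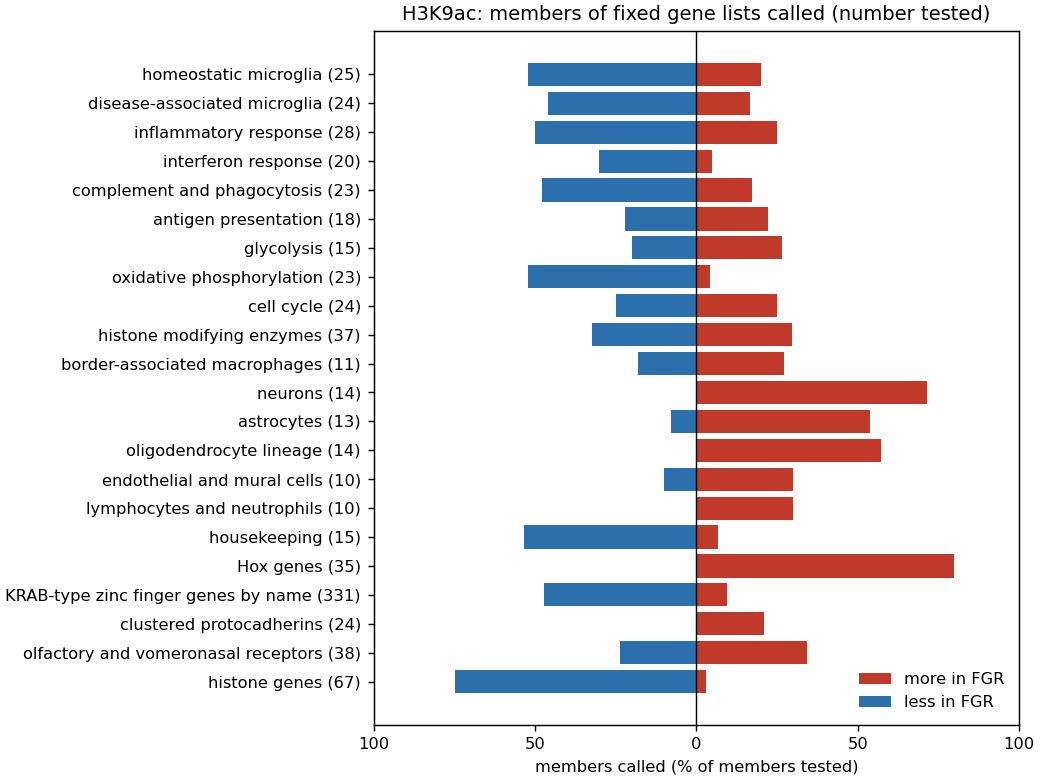
Percent of the tested members of each fixed gene list with less (blue) or more (red) H3K9ac coverage in FGR by limma, with the number tested in brackets. Of Hox genes 28 of 35 had more and of histone genes 50 of 67 had less, and both directions were kept after quantile normalization; those of disease-associated microglia, antigen presentation, endothelial, border-associated macrophage, cell cycle, glycolysis, histone modifying enzyme and receptor genes varied with scaling.

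H3K27ac, a mark of active enhancers and promoters, had shorter peak coverage around most genes in FGR. Its peaks were also narrower there, with median widths of 314 to 365 bp against 825 to 919 bp in Ctrl, beside a smaller fragment setting. Narrower calls and less of the mark were not told apart, for the genes and lists below as well. Map3k3, a kinase gene of the MAPK pathway (chromosome 11, 106084587 to 106156656), fell from 9.33 ± 0.294 kb to 2.59 ± 0.34 kb (n = 4 each; limma adjusted p = 9.71e-08). Irf2bp2, a transcriptional corepressor gene, fell from 9.69 ± 0.118 kb to 4.09 ± 0.349 kb, and Tmem119 from 7.11 ± 0.486 kb to 1.41 ± 0.519 kb. Of 11876 genes, 9687 were covered less and 22 more in FGR by limma, with a median difference of −0.707 kb. The 22 became 6 with lists of equal length, 12, 14 and 9 without Ctrl replicates 1, 2 and 4, 13 without FGR replicate 1 and 239 in the depth-matched setting. After quantile normalization, 1488 were higher and 1344 lower.

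H3K27ac fell at 25 of 26 homeostatic microglia genes, with list medians of 6.87 kb in Ctrl and 4.39 kb in FGR, and after quantile normalization 9 were lower and 6 higher. Cx3cr1 fell from 9.77 ± 0.183 kb to 6.33 ± 0.476 kb, Csf1r, with a window shared with Hmgxb3, from 8.38 ± 0.535 kb to 4.69 ± 0.678 kb and Sall1 from 8.02 ± 0.309 kb to 4.75 ± 0.333 kb. P2ry12 fell from 9.69 ± 0.274 kb to 7.95 ± 0.45 kb, a direction that turned after quantile normalization without passing the test. The list fell more than other genes (camera adjusted p = 0.000321; adjusted p = 0.481 with an estimated correlation). Regions called only in Ctrl lay at Tgfbr1, a receptor of the TGF-β pathway (chromosome 4, 47394289 to 47396659), and at Itgam, which encodes CD11b (chromosome 7, 128113834 to 128116194), both of this list.

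The fall of H3K27ac took in 18 of 21 disease-associated microglia genes, 19 of 24 inflammatory, 20 of 23 complement and phagocytosis, 14 of 20 interferon, 14 of 17 antigen presentation and 6 of 9 border-associated macrophage genes. Ctsd, a lysosomal protease gene, fell from 9.82 ± 0.0435 kb to 5.93 ± 0.608 kb, Sirpa, a receptor that restrains phagocytosis, from 9.68 ± 0.141 kb to 4.95 ± 0.578 kb, B2m from 7.97 ± 0.189 kb to 3.55 ± 0.421 kb and Tnfaip3, an inhibitor of NF-κB signalling, from 5 ± 0.067 kb to 2.69 ± 0.334 kb. Apoe fell from 2.81 ± 0.145 kb to 1.56 ± 0.63 kb. Trem2 (4.33 ± 0.256 kb to 3.58 ± 0.279 kb) and Il1b (2.79 ± 0.205 kb to 1.74 ± 0.223 kb) fell as well, and both directions turned after quantile normalization, without passing the test at Il1b. After that normalization, 4 complement and phagocytosis genes were higher and 3 lower, 2 interferon genes higher and 1 lower, and the other 4 lists kept more genes lower than higher.

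Metabolic and general lists fell too, with 12 of 12 glycolysis, 21 of 23 oxidative phosphorylation, 15 of 23 cell cycle, 15 of 16 housekeeping and 35 of 36 histone modifying enzyme genes. The demethylase gene Kdm4a fell from 4.02 ± 0.1 kb to 2.13 ± 0.251 kb. The enzymes fell by more kb than other genes (camera adjusted p = 0.0451; adjusted p = 0.481 with an estimated correlation). Histone genes fell at 63 of 64, but after quantile normalization 27 were higher and 1 lower. Zfp genes fell at 221 and rose at 2 of 302 (217 and 2 adjusted over the list alone), less than other genes did (camera adjusted p = 0.0444; adjusted p = 0.481 with an estimated correlation), and after quantile normalization 62 were higher and 12 lower. Zfp652 fell from 4.47 ± 0.191 kb to 1.45 ± 0.318 kb. All 21 protocadherins tested, many of which share a window, fell, but in the depth-matched setting 20 of 21 were covered more in FGR. Olfactory and vomeronasal receptors fell at 10 of 15 and turned after quantile normalization, with 2 higher and 1 lower. The 1 Hox gene tested did not pass.

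Few members of lists of other cell types had H3K27ac, which fell at 1 of 2 neuronal genes tested, 2 of 4 astrocyte, 4 of 4 oligodendrocyte, 2 of 5 endothelial and mural and 3 of 5 lymphocyte and neutrophil genes. Prox1, a transcription factor of dentate granule neurons, fell from 2.39 ± 0.0853 kb to 1.36 ± 0.316 kb. Aldoc, an astrocyte enzyme gene with a window shared with Pigs and Spag5, fell from 0.866 ± 0.0484 kb to 0. Kdr, an endothelial growth factor receptor gene, fell from 5.47 ± 0.362 kb to 4.48 ± 0.293 kb and rose after quantile normalization. The endothelial list fell less than other genes (camera adjusted p = 0.0451; adjusted p = 0.481 with an estimated correlation), and after quantile normalization 2 of its genes were higher. Adjusted over the list alone, the counts of lists other than Zfp genes were those over all genes. The 22 genes covered more had short peaks, as at Zfp599 (0 to 0.392 ± 0.147 kb), Cyp2u1 (0 to 0.309 ± 0.0488 kb), Cd69, a lymphocyte activation marker (0 to 0.29 ± 0.124 kb), and Plk1, a mitotic kinase gene (0.0668 ± 0.134 kb to 0.342 ± 0.0143 kb).

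H3K27ac peaks were more numerous in FGR, 66006 ± 10076 against 48483 ± 1768 (n = 4, exact permutation p = 0.0286), but covered less of the genome, 35.6 ± 3.96 Mb against 64.2 ± 1.27 Mb (log2 difference −0.86, SE 0.0855, exact p = 0.0286). Median peak widths were 825 to 919 bp in Ctrl and 314 to 365 bp in FGR, beside a smallest width of 267 to 284 bp and 148 to 151 bp. The log2 difference of peak numbers was 0.15 at the stricter threshold (exact p = 0.171) and 0.11 with peaks stitched over gaps (exact p = 0.486). Genes with a peak at an end fell from 10604 ± 91.7 to 10058 ± 388 (n = 4, exact p = 0.0286), and in the depth-matched setting numbered 9510 and 9992 (exact p = 0.114). The share of peaks at gene ends was 23.7 ± 0.491% and 24.2 ± 2.11% (n = 4, exact p = 0.686), with lists of equal length 24.6% and 28.6%, and in the depth-matched setting 36.0% and 24.6%, turned in direction (exact p = 0.0286 for both settings). A total of 979 regions were called only in Ctrl and 130 only in FGR. They numbered 2621 and 39 with lists of equal length, and 8376 and 56 with at least 50% of a region covered. In the depth-matched setting they numbered 36 and 1516, but its scaling took in the fragment setting as well as depth. Leaving out FGR replicate 2 gave 1950 and 384, and leaving out Ctrl replicate 2 gave 1511 and 206. Ctrl regions numbered 1616 without Ctrl replicate 3, and FGR regions 241 and 265 without FGR replicates 3 and 4. Such rises follow in part from the looser rule when a library is left out.

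The H3K9me3 lists, of a mark of heterochromatin, held fewer peaks in FGR as deposited, but the groups had been called at different thresholds. The direction turned when the deposited peaks were filtered at a common −log10 q. This filter removed only Ctrl peaks, since the FGR lists already ended above it. It does not stand in for calling both groups alike, so neither direction shows a difference in the mark. As deposited, 429583 ± 75873 peaks in Ctrl and 18818 ± 3753 in FGR (n = 3, exact permutation p = 0.1, the smallest this design allows) covered 398 ± 98.99 Mb and 12.4 ± 2.68 Mb. At a −log10 q of at least 1 in both groups, 97.7 ± 5.03 and 18818 ± 3753 peaks were left (n = 3, exact p = 0.1), covering 0.188 Mb and 12.4 Mb. Of 12489 genes tested by limma as deposited, 7826 were covered less and 15 more, with a median difference of −7.00 points of the gene body. Without FGR replicates 1, 2 and 3, the genes covered less were 4924, 4905 and 5042. They were 13458 with 10 kb on each side of the gene body and 3307 with peaks in at least 4 libraries. With replicate 4 included, which mixed narrow and broad lists, limma called 0 more and 0 less. At an unadjusted p under 0.05 these were 15 and 6222. At the common threshold 5 of 2261 were covered less and 878 more, and after quantile normalization of the deposited lists 1436 were lower and 1824 higher.

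As deposited, H3K9me3 fell at 229 of 293 Zfp genes (234 adjusted over the list alone), a family in which many genes lie in clusters under this mark. Zfp988 (chromosome 4, 147305604 to 147334067) had 94.8 ± 0.365% of its body covered in Ctrl and 7.27 ± 2.08% in FGR (n = 3 each; limma adjusted p = 3.87e-06), and Zfp978 89.5 ± 0.597% and 23.1 ± 0.575%. Zfp genes fell by more points than other genes (camera adjusted p = 9.9e-08; adjusted p = 0.769 with an estimated correlation). List medians were 21.7% in Ctrl and 0.169% in FGR, whose lists were cut at another threshold. The greater fall therefore follows from the Ctrl coverage of this list and does not show a difference in the mark. At the common threshold 41 of 96 Zfp genes were covered more, and Zfp978 and Zfp988 were covered in FGR alone. Olfactory and vomeronasal receptors fell at 231 of 565 (202 adjusted over the list alone) and protocadherins at 39 of 52 (40 adjusted over the list alone), while at the common threshold 10 of 25 and 11 of 33 were covered more. Olfr108 and Vmn1r151 were covered over 100% in Ctrl and listed at 0 in FGR. The longest region called only in Ctrl, 43400 bp on chromosome 7 from 23224852 to 23268251, lay at Vmn1r166, and another at Zfp759 on chromosome 13 from 67132120 to 67161004.

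Among the other gene lists, FGR medians of deposited H3K9me3 were 0 except for neurons (0.0392%) and histone genes (13.3%). Falls there mostly followed Ctrl coverage. Members of these gene lists fell in part. The counts were 10 of 11 neuronal genes, 8 of 10 endothelial and mural, 5 of 6 astrocyte, 1 of 5 oligodendrocyte, 6 of 7 border-associated macrophage, 4 of 11 homeostatic microglia, 5 of 10 disease-associated microglia, 4 of 9 inflammatory, 6 of 12 interferon, 13 of 21 complement and phagocytosis, 3 of 8 antigen presentation, 2 of 5 glycolysis, 2 of 5 oxidative phosphorylation, 2 of 7 cell cycle, 13 of 23 histone modifying enzyme, 3 of 6 housekeeping, 1 of 9 Hox and 1 of 4 histone genes, and 0 of 3 lymphocyte and neutrophil genes by limma, 1 of them at an unadjusted p under 0.05. Adjusted over the list alone, they were 3 for homeostatic microglia, 14 for complement and phagocytosis, 0 for Hox (2 at an unadjusted p under 0.05) and 0 for oligodendrocyte genes (1 at an unadjusted p under 0.05) by limma, and the same for the others. Histone genes fell less than other genes (camera adjusted p = 0.0446; adjusted p = 0.769 with an estimated correlation). No list had more members higher than lower as deposited, while quantile normalization left more higher than lower in 8 of the 22 lists and more lower than higher in 8. The synaptic genes Syt1 (24.9 ± 6.67% to 0.0392 ± 0.0679%) and Grin2b (13.3 ± 2.98% to 0.104 ± 0.0411%) fell, the mean difference of the latter turning under quantile normalization and at the common threshold without passing the test. Hdac2 went from 26.6 ± 3.63% to 0, P2ry12 from 8.09 ± 2.78% to 0 and Cx3cr1 from 5.07 ± 3.06% to 0, while Il1b, with 12.9 ± 9.62% and 0, did not pass (adjusted p = 0.0668).

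In spite of the shorter lists, 15 genes had more H3K9me3 in FGR. Flg, for the skin protein filaggrin, had 23.3 ± 8.88% in Ctrl and 54.8 ± 5.28% in FGR, and Eppk1, for epiplakin (chromosome 15, 76101488 to 76120195), 1.34 ± 2.32% and 14.6 ± 3.02% (n = 3; limma adjusted p = 0.00476). Ahnak2 had 1.61 ± 1.85% and 10 ± 2.41%, and Mepe, for a bone matrix protein, 1.39 ± 1.4% and 9.19 ± 2.43%. The mean difference turned for Flg with 5 kb windows at gene ends, and for Mepe with those windows and with 10 kb added to the gene body, without passing the test. Regions called only in FGR numbered 321 and only in Ctrl 120705, against 6474 and 15 at the common threshold. Leaving out each library in turn gave 509 to 623 in FGR, and leaving out Ctrl replicate 3 gave 203679 in Ctrl. An FGR region of 3125 bp lay in Eppk1, on chromosome 15 from 76102743 to 76105867. Repeated sequence and the uniqueness of alignment could not be checked for the genes and regions with more H3K9me3 in FGR. Genes with a peak at an end numbered 6121 ± 1061 and 332 ± 81.5 (n = 3, exact p = 0.1), and the share of peaks at gene ends was 1.83 ± 0.0742% and 1.98 ± 0.112% (n = 3, exact p = 0.3).

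**Figure D4:**
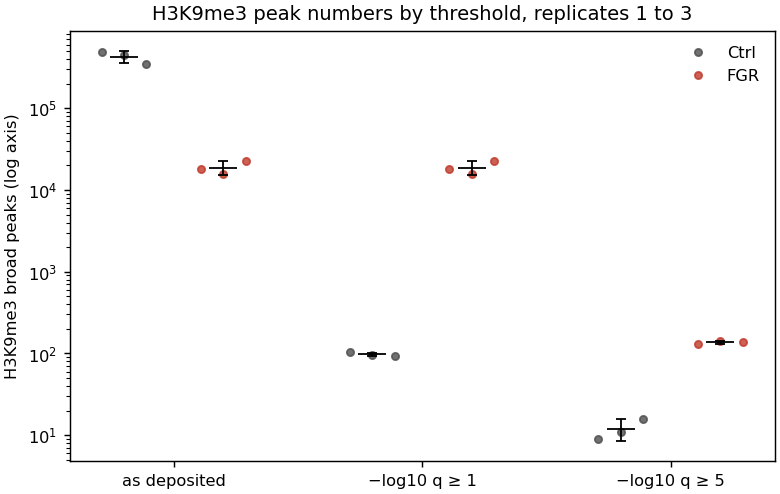
Number of H3K9me3 broad peaks per library on a log axis, as deposited and at −log10 q of at least 1 and at least 5, for replicates 1 to 3 of Ctrl (grey) and FGR (red), with the mean and SD as bars. The Ctrl mean fell from 429583 to 97.7 at a −log10 q of at least 1, and the FGR mean stayed at 18818.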

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

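Within groups of 4 libraries, single libraries that stood apart from the other 3 by Dixon's test at 95% were looked for in 186 groups of values, and 15 were found. Chance gives about 1 in 20 groups, but in 7 of the 15 the other 3 libraries were at 0, where any value passes, so their number was not set against chance. The tests on single genes, which cover the genes named in the text, and the comparison of the narrow H3K9me3 lists were chosen only after the results were seen.

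For H3K27ac, Kdm4a had 4.169 kb in Ctrl replicate 1, with the nearest other Ctrl library at 3.98 kb, Trem2 4.714 kb in Ctrl replicate 2 (nearest 4.238 kb), and Plk1 0.267 kb in Ctrl replicate 3 with the others at 0. For H3K4me3, genes with a peak at an end numbered 10411 in Ctrl replicate 1, with the nearest other library at 10015. Adrb1 had 2.547 kb in Ctrl replicate 3 (nearest 2.903 kb) and Prox1 4.201 kb in FGR replicate 1 (nearest 4.745 kb). Single Ctrl libraries had short H3K4me3 peaks where the others had none, with 0.561 kb at Apoe in replicate 2, 0.291 kb at Mrc1 in replicate 3, 0.305 kb at Nefh in replicate 1 and 0.117 kb at Tsc22d3 in replicate 1.

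For H3K9ac, Apoe was shortest in replicate 4 of both groups, with 1.915 kb in Ctrl (nearest 2.503 kb) and 3.744 kb in FGR (nearest 4.637 kb). Trem2 had 3.72 kb in Ctrl replicate 2 (nearest 3.413 kb). Hoxa6 had 0.265 kb in Ctrl replicate 3 and Ifit3 0.254 kb in FGR replicate 1, with the other libraries of each group at 0.

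Replicate 4 of H3K9me3, which came as narrow peaks and was left out of the main H3K9me3 comparison, held 257 peaks in Ctrl and 11204 in FGR. The lowest −log10 q of these lists was 1.398 in Ctrl and 1.302 in FGR. With a single library per group there is no test of this difference.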

How the results depend on the processing

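The common q threshold, depth-matched lists, stitched peaks, a single gene end and replicates 1 to 3 of both groups were chosen only after the results were seen; the other settings were planned. Of the results that answer a comparison, 334 values under alternatives kept their direction, side of the threshold or size, 76 moved, 20 turned, 3 no longer passed their threshold and 2 newly passed. Of values of single genes and lists, 2011 did so, 74 newly passed their threshold, 105 no longer passed and 22 turned. The cause was not tested unless the setting itself shows it. Depth is unknown, and the lower background of FGR libraries limits all comparisons of list length. Differences below are FGR minus Ctrl, on the log2 scale for peaks and covered genome, in points for shares at gene ends, and in numbers for genes with a peak at an end.

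Quantile normalization gave 2220 genes more and 3398 less for H3K4me3, 1488 and 1344 for H3K27ac, and 1824 and 1436 for H3K9me3, since it removes a shift common to all genes. It turned H3K4me3 at Csf1r (−0.81 kb), Cx3cr1 (−0.0273 kb) and Trem2 (−0.749 kb), H3K27ac at Il1b (0.0866 kb), Kdr (1.22 kb), P2ry12 (0.433 kb) and Trem2 (1.07 kb), and H3K9me3 at Grin2b (2.16 points) and Zfp978 (9.66 points). Equal list lengths turned the share at gene ends for H3K4me3 (3.21) and H3K9ac (3.24), raised it for H3K27ac (4.02), and gave −0.0556 for H3K9me3. They changed covered genome to −0.36 for H3K9ac (42.1 and 33.0 Mb, exact p = 0.0286) and −0.38 for H3K9me3, and genes with an H3K9me3 peak at an end to −29.0. Regions in FGR and in Ctrl alone became 936 and 178 for H3K4me3, 39 and 2621 for H3K27ac, and 3996 and 226 for H3K9me3, and 4060 and 6447 for H3K9ac, where the order turned. Gene calls became 168 less for H3K4me3, 6 more for H3K27ac, and 105 more and 26 less for H3K9me3.

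The stricter threshold gave peak differences of 0.34 for H3K9ac (exact p = 0.0857), 0.15 for H3K27ac (exact p = 0.171) and 3.55 for H3K9me3, and covered genome of −0.22 for H3K9ac and 3.4 for H3K9me3. For H3K9me3 it also gave 7.67 genes with a peak at an end, a share of 2.41, 63 regions in FGR and 3 in Ctrl alone, 0.212 points at Zfp978, and 0 genes less by limma, with 0 also at an unadjusted p under 0.05, among 31 tested. It left 7 H3K4me3 regions in Ctrl alone, 4060 H3K9ac regions in FGR and 3677 in Ctrl alone, 39 H3K27ac regions in FGR alone, and 6 genes with more H3K27ac. With at least 50% of a region covered, 5846 H3K9ac regions were in FGR and 7598 in Ctrl alone, also with the order turned, 56 and 8376 H3K27ac regions in FGR and Ctrl alone, and 27939 H3K9me3 regions in Ctrl alone.

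In depth-matched lists, the share at gene ends was −27.3 for H3K9ac and −11.4 for H3K27ac. Genes with an H3K27ac peak at an end turned to 482, and 239 genes had more H3K27ac. The scaling took in the fragment setting, so for H3K4me3 and H3K27ac it was not of depth alone. Widths of the peaks kept were left as deposited, so covered lengths were not matched for depth in any mark. Regions in FGR and in Ctrl alone were 22245 and 1 for H3K4me3 and 1516 and 36 for H3K27ac, and 651 in Ctrl alone for H3K9ac. Stitching gave an H3K27ac peak difference of 0.11. A single gene end gave 2882 genes with more H3K9ac, 1 with less H3K4me3, and −0.549 kb of H3K9ac at Tmem119. Gene ends of 5 kb gave 2 genes with less H3K4me3, 9 with more H3K9me3, −1.29 kb of H3K9me3 at Flg and −0.647 kb at Mepe, and ends of 1 kb gave 0.0312 kb of H3K27ac at Trem2. For H3K9me3, 10 kb around gene bodies gave 13458 genes less and −3.61 points at Mepe, and peaks in at least 4 libraries gave 3307 less. Replicates 1 to 3 gave 9 genes with more H3K27ac.

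The common q threshold removed no FGR peak, so it is not a calling of both groups alike. With it, H3K9me3 differences were 7.57 for peaks and 6.02 for covered genome. Those for genes with a peak at an end and for the share were 329 and −2.53. Regions in FGR and Ctrl alone were 6474 and 15, gene calls 878 more and 5 less, and differences 0.104 points at Grin2b, 23.1 at Zfp978 and 7.27 at Zfp988. With replicate 4 included, the H3K9me3 differences were −2.03, −2.36, −4309.5 and −0.879. Limma then called 0 genes more and 0 less, with 15 and 6222 at an unadjusted p under 0.05. This setting mixed narrow with broad lists and lists cut at different thresholds, and these were not tested apart. Limma's fry, which tests lists on their own and not against other genes, gave the opposite direction to camera for H3K4me3 at Hox genes (adjusted p = 7.74e-06) and neurons (adjusted p = 5.06e-06) and for H3K27ac at Zfp genes (adjusted p = 8.36e-06) and endothelial genes (adjusted p = 0.0346). With an estimated correlation, 20 list calls were lost.

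Leaving out each library in turn gave 9 to 27 genes with more H3K27ac (9 without Ctrl replicate 4), 154 to 384 H3K27ac regions in FGR and 1034 to 1950 in Ctrl alone (both highest without FGR replicate 2), and a share of H3K27ac peaks at gene ends of −0.439 to 1.28, negative without FGR replicate 4. It gave 0 to 1 genes with less H3K4me3, 9783 to 14489 H3K9ac regions in FGR alone, and H3K9ac covered genome of −0.0820 to 0.101, negative without Ctrl replicates 1 or 4 or FGR replicates 1 or 2. For H3K9me3 it gave 4905 to 9690 genes less (lower without any FGR library), 509 to 623 regions in FGR alone and 122746 to 203679 in Ctrl alone. Region counts tend to rise when a library is left out, since the rule then asks for fewer libraries.

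Replicate numbers do not show a pairing of libraries. Correlations of deviations between Ctrl and FGR libraries ran from −0.041 to 0.0444, and libraries did not all correlate best with their own number. With the replicate number as a block, limma gave 13203 genes more and 0 less for H3K4me3 (0 less also at an unadjusted p under 0.05), 4315 and 4422 for H3K9ac, 16 and 9412 for H3K27ac, and 12 and 5708 for H3K9me3. Under this block, 2 named genes no longer passed and 4 lists newly did.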

Other observations

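Of the tests in this part, the share of lost H3K9ac peaks in depth-matched lists and the comparison of FGR H3K9ac libraries with each other were set before their results were seen. All others, including the X chromosome and overlap comparisons, the background test, the other correlations, the splits and the depth-matched and common q settings, were chosen only after the result was seen, and the bound of the test on H3K27ac at neuronal and glial genes was changed after its value was seen.

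H3K4me3 on the X chromosome was low in Ctrl relative to autosomes. Of 966 X genes, 13.5 ± 1.82% had an H3K4me3 peak at an end in Ctrl and 43.6 ± 0.579% in FGR, against 48.3 ± 0.901% and 61.3 ± 0.497% of 20665 autosomal genes. The ratio of X to autosomes was 0.279 ± 0.0323 in Ctrl and 0.711 ± 0.00648 in FGR (n = 4, exact permutation p = 0.0286), and 0.265 and 0.626 with lists of equal length. For H3K9ac the ratio was 0.6 ± 0.00219 in Ctrl and 0.612 ± 0.00728 in FGR, and for H3K27ac 0.607 ± 0.00623 and 0.567 ± 0.0117 (n = 4, exact permutation p = 0.0286 each), and with lists of equal length the H3K9ac difference turned to 0.601 and 0.582. Bcor, Brwd3, P2ry10b and Tsc22d3, among the H3K4me3 genes with the smallest p, lie on X.

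Genes that lost H3K9ac also lost H3K27ac in 4231 cases among 11725 genes tested for both, where independent lists would share 3837, and genes that gained H3K9ac lost H3K27ac in 1457 cases, where 1724 would be shared. H3K4me3 was longer at 4627 of 4655 genes with less H3K9ac, with 4468 for independent lists. It was longer at 3475 of 3734 genes with more H3K9ac, with 3584 for independent lists. Ahnak2 held gains of both H3K9me3 and H3K9ac in FGR, with an H3K9ac region of 8981 bp called only in FGR on chromosome 12 from 112775792 to 112784772. A stretch of chromosome 17 without a protein-coding gene, from 39843022 to 39848767, carried the longest H3K9me3 region called only in FGR, and an H3K27ac region called only in FGR began at 39843070. Repeated sequence and the uniqueness of alignment could not be checked there or at Ahnak2, so these calls need not reflect the marks. Across genes, which are not independent replicates, Ctrl H3K9ac libraries correlated with Ctrl H3K27ac libraries at a mean r of 0.929, with FGR H3K4me3 libraries at 0.908 and with FGR H3K9ac libraries at 0.757. FGR H3K4me3 libraries correlated with Ctrl H3K4me3 libraries at 0.822.

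For the rise of H3K4me3 in FGR, deeper FGR libraries are argued against by the lowest background per 100 bp of fragment, which grows with depth. It was 1.0125 to 1.282 in Ctrl and 0.568 to 0.786 in FGR libraries, a log2 difference of means of −0.826, though it measures depth only indirectly. A candidate explanation that stays open is a higher enrichment over background of all FGR H3K4me3 libraries, with 100% of housekeeping genes covered more. The highest fold per library was 9.52 to 9.71 in Ctrl and 50.8 to 62.9 in FGR. A change in the mark itself with growth restriction also stays open and was not tested, because background and fragment setting separate the groups completely. For the shorter H3K27ac coverage in FGR, narrower peak calls and a change in the mark likewise stay open and were not tested apart.

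The loss of H3K9me3 peaks in FGR may come from the thresholds of the lists, which differed between the groups. At a common q threshold the log2 difference turned from −4.52 to 7.57. That filter removed only Ctrl peaks, so it cannot show which group would hold more peaks if both were called alike. The narrow lists of replicate 4, called at like thresholds, also held more peaks in FGR. Whether the mark differed between the groups was not tested, since the lists hold no signal outside peaks. The 10 splits of 6 libraries are too few for a share under 0.05, with 7841 genes called in the real split and 1 in the highest other.

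H3K9ac was gained at neuronal and Hox genes and lost at homeostatic microglia and inflammatory genes. For the gained part, 1308 genes had a peak in all FGR and no Ctrl library, against 107 the other way. Shallower FGR libraries would give the reverse order. The FGR lists were already longer as deposited (means of 72648 against 45521 peaks), so this order follows from list length. It is no separate evidence against shallower libraries. For the lost part, neither shallower FGR libraries nor narrower peak calls can be told apart from a true loss. Of the 107 lost genes, 51.9% (48.6 to 54.2% per library) also lost their peak in depth-matched Ctrl lists, on both sides of the bound. Chromatin of other brain cells could still contribute, since at neuronal and glial genes the H3K27ac lists showed 0 of 52 genes gained and 1 lost, a net −1 and too few to decide. A mix-up of mark labels, which would bear on H3K4me3 as well, cannot be excluded either, because the correlations across genes disagree. Of the Ctrl marks, FGR H3K9ac libraries were closest to H3K9ac (mean r of 0.757, against 0.693 for H3K27ac and 0.65 for H3K4me3), but FGR H3K4me3 libraries were also closest to Ctrl H3K9ac (0.908, against 0.822 for their own mark). Ctrl H3K4me3 libraries correlated with each other at a mean r of 0.872, and Ctrl H3K9ac libraries at 0.977. FGR H3K27ac libraries were closest to their own mark in Ctrl (0.935, against 0.896 for H3K9ac and 0.662 for H3K4me3), so the doubt is between H3K4me3 and H3K9ac. FGR H3K9ac libraries correlated less with the closest other mark (mean r of 0.792) than with each other (lowest r of 0.933), but this does not decide it, since libraries of a single preparation can correlate best among themselves under any label. Another antibody lot or preparation batch and growth restriction itself stay open and were not tested.

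Splits of the 8 libraries of a mark show that the groups differ, but not why, since background and fragment setting also separate them completely. Mixed splits hold that difference within their groups, so few calls could be foreseen there. In 1 of 35 splits, the real one, as many genes were called, with 13410 for H3K4me3, 9128 for H3K9ac and 9709 for H3K27ac, and 0 in the highest other split of each. For regions called in a single group the real splits gave 14033, 14659 and 1109, and the highest others 30, 168 and 335.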
